A study of Mus musculus with 6 samples.

How the data were processed

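RNA was measured in 6 cultures of 393P, a mouse lung cancer cell line. Per the labels, 3 cultures carried the empty pcDNA control vector and 3 carried a vector for stable, constitutive expression of Zeb1, and both kinds of cell were profiled in triplicate cultures. Total RNA was copied into biotin-labelled cRNA for Affymetrix expression arrays, per the labels' protocols. Each array is 1 sample, so the arrays are replicate cultures of stably transfected cells, and how many separate transfections lie behind each group is not given in the sources used here. The p-values therefore measure the spread between cultures.

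The deposited table held log2 values for 45101 probe sets on each of the 6 arrays. The submitters' processing notes name MAS5, a method that summarises each probe set on its own array and then scales the array, and they give no version in the sources used here. Once taken out of log2, 100% of the values were multiples of 0.1 within a tolerance of 0.01 multiples, and the linear mean with 2% trimmed from each end was 500 on each array, so the arrays had been scaled to a common mean before deposit. Detection calls were not used here. The table lacked 2 values, both on control vector replicate 2, which were placed at the floor described next.

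Signals below the 25th percentile of all values pooled over the 6 arrays were raised to it (log2 4.45, linear signal 21.8). The share of probe sets at this floor was 24.0% to 26.4% per array. MAS5 signals this low carry little but noise, and the floor keeps that noise from looking like fold changes; it also makes every change to or from the floor a lower bound. A probe set was tested if its signal reached its array's median on at least 3 of the 6 arrays. Control probe sets (64), probe sets with several gene symbols (932) and probe sets with no symbol here (9160) were left out, which left 34945 with 1 symbol. Symbols came from the platform annotation and were looked up through the Entrez identifier in the RefSeq gene table of assembly GRCm38.p6. That table held 34741 of the 34945 probe sets, and 0 symbols changed. From it only names and the order of neighbouring genes were used. The filter passed 20594 probe sets, and each gene was represented by its probe set with the highest mean log2 signal, which gave 11893 genes. Among the called genes, 76 had another tested probe set called in the opposite direction.

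Zeb1 vector was compared with control vector with limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0 to read the labels; lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. All adjusted p-values for genes are from this moderated test. Those of single probe sets of Zeb1 and Zeb2 are from the same test over all probe sets that passed the filter, to which the Zeb1 probe sets below it were added for Zeb1. Of 62 named genes with several tested probe sets, 36 had another whose log2 change was over 1.5 times larger or smaller, or of the other sign. A gene is said to rise or fall only if it passed. Errors of log2 changes are limma's moderated standard errors (SE). With 3 arrays per group the number of arrays limits the precision: the median SE of a log2 change was 0.129. A gene at the floor on every array of a group has only a bound, written as at least N-fold. Where only 1 or 2 arrays of a group lay at the floor the change is a lower bound too, given that floor, and such folds are written in the same way, as are folds of genes whose lower group mean lies below the pooled 50th percentile (6.32), where signal and background are hard to part. Of 18 such named genes that were called and lay above the floor on every array, 4 had a log2 change over 1.5 times that with the floor at the 50th percentile (Cd274, Itgb6, Tap2 and Wnt5a). Bounds move with the floor. For the named genes with arrays at the floor, log2 changes were 1.11 times (Bgn) to 5.35 times (Tagln) those with the floor at the 50th percentile. Among genes given by log2 changes alone, arrays at the floor make the change a bound for Irs2, Igtp, Ccl5, Csf3 and Egln3 and for the Zeb2 probe sets so marked. The gene lists were fixed before the data were examined, 28 in all, and 25 had at least 5 tested members. They were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, with camera at an estimated correlation, and with fry, each adjusted over the 25 lists. Camera works on moderated statistics, so its direction can differ from the sign of a list's mean log2 change. The difference between the mean of the epithelial junction list and the mean of the mesenchymal list was compared by a two-sided exact permutation test over the arrays, whose smallest possible p is 0.1.

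The genes named were chosen by a rule also fixed before the data were examined: every Zeb1 probe set, 15 fixed genes, the 10 largest rises and falls among called genes above the floor on at least 1 array of each group with no overlap between groups, the 5 largest bounds each way, and up to 4 called members per list with the largest change. Genes outside it are marked as chosen after their values were seen. Predicted genes were passed over.

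The fit was tested on simulated data made from the real means and SDs of the 11893 genes. In these data 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, all drawn from genes above the median mean signal. The shares recovered and false therefore do not cover dimmer genes, or data in which as many genes change as here. For Zeb1 vector against control vector it recovered 83.6% of the genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold, and 4.19% of all calls were false. The alternatives covered the floor, the scaling, the filter, the variance model, array weights, the choice of probe sets, the replicate number as a block and each array left out in turn. A floor at the 50th percentile and changes taken relative to neighbouring genes were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.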

Results

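The series compared mouse 393P lung cancer cells that stably carried an empty pcDNA vector with the same cells made to express Zeb1, a zinc-finger repressor known for silencing epithelial genes. There were 3 control vector arrays and 3 Zeb1 vector arrays, 1 per culture. Over probe sets above the floor, arrays of 1 group correlated at r = 0.959 to 0.964 and arrays of different groups at r = 0.893 to 0.899, across probe sets, which are not independent replicates. Each array had been scaled to the same trimmed mean linear signal of 500. The question, as the labels pose it, is which transcripts differ once Zeb1 is expressed.

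Zeb1 itself was read by 4 probe sets. On the probe set that stood for the gene the log2 signal went from 4.47 ± 0.034 (SD, n = 3) in control cells, where 2 of the 3 arrays were at the floor, to 9.69 ± 0.096 (SD, n = 3) in Zeb1 cells, a rise of 5.23 (SE 0.176, adjusted p = 2.67e-08) or at least 37.4-fold. On another it rose by 1.17 (SE 0.295, adjusted p = 0.00911), from 6.23 ± 0.524 to 7.40 ± 0.292. The remaining 2 lay at the floor on all 3 control arrays and did not pass the filter, and their log2 changes were 0.35 (adjusted p = 0.613) and 0. Which part of the transcript each probe set reads, and whether the vector's copy carries it, is not known here.

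Most of the tested genes of epithelial cell junctions and polarity fell in Zeb1 cells, 29 of 34, and Cdh2 and Vim rose, by 4.88 and 2.86 on the log2 scale. Of the 11893 tested genes 6004 were called (50.5%), of which 3139 rose and 2865 fell. At least 2-fold changes were seen in 1880 called genes, 1071 up and 809 down. Changes of at least 16-fold were seen in 64 that rose and 82 that fell. The 2 groups of arrays did not overlap in 58.2% of the genes, where chance gives 10%. The median log2 change of all tested genes was 0.01 and the median SD within groups was 0.157.

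**Figure D1:**
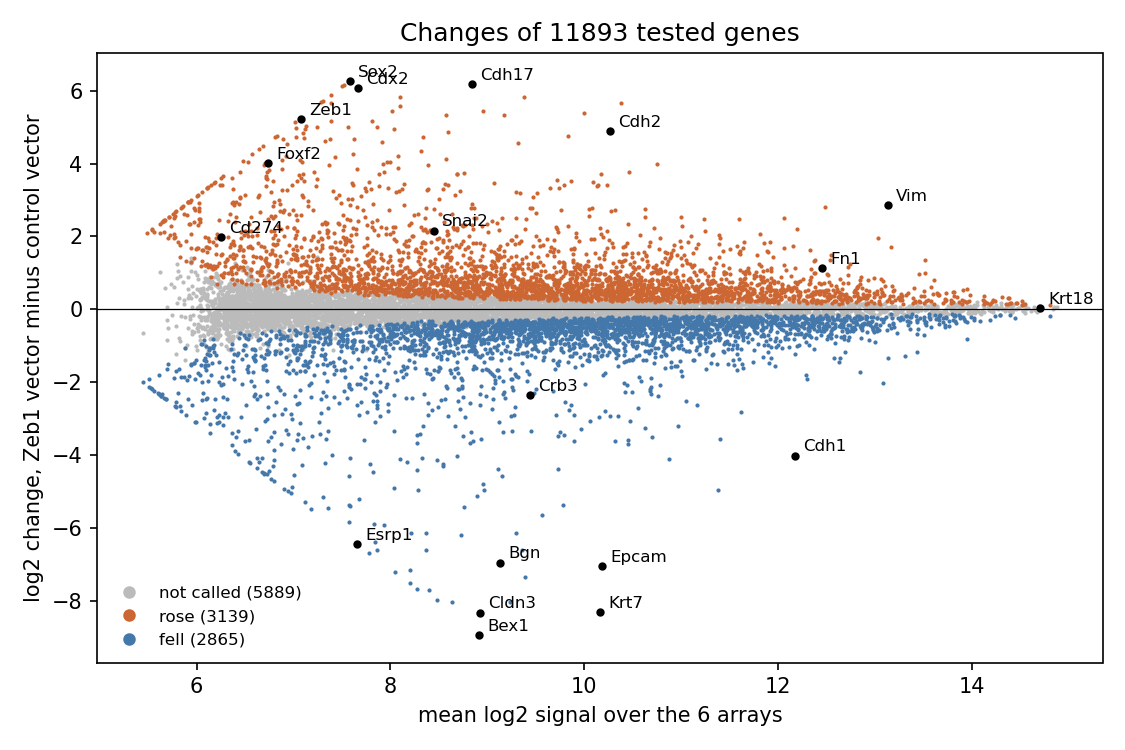
Log2 change (Zeb1 vector minus control vector) of each of the 11893 tested genes against its mean log2 signal over the 6 arrays, with genes that rose in orange, genes that fell in blue and genes not called in grey. Named genes are black dots: Krt18 lies at the bright end with a change of 0.03, while Cldn3, Krt7 and Bex1 lie more than 8 below 0, and the slanted edges hold genes at the floor in 1 group.

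The 10 largest falls among genes with at least 1 array of each group above the floor included 3 claudins, the keratin Krt7 and the epithelial adhesion molecule Epcam. Above the floor on every array, Krt7 was at least 318-fold lower (14.33 ± 0.030 to 6.01 ± 0.262, SD, n = 3 each, adjusted p = 8.93e-11), and Epcam was 133-fold lower, or 10.0-fold on its other probe set. The claudins Cldn4 and Cldn7 were at least 261-fold and 163-fold lower, with low signals in Zeb1 cells (5.22 ± 0.751 and 5.72 ± 0.697). With the floor at the 50th percentile the log2 changes of Krt7, Cldn4 and Cldn7 were -8.00, -6.93 and -6.74. At the floor on 2 of the 3 Zeb1 arrays were Cldn3, a sealing protein of tight junctions, at least 319.7-fold lower (13.09 ± 0.102 to 4.77 ± 0.558, adjusted p = 2.64e-09), the epithelial vesicle GTPase Rab25 (at least 261-fold), the potassium channel Kcnk1 (at least 253-fold), Ctla2a (at least 209-fold) and the surface antigen Psca (at least 143.5-fold). The proteoglycan biglycan, Bgn, at the floor on 1 Zeb1 array, was at least 123.5-fold lower (12.61 ± 0.061 to 5.66 ± 1.071). These bounds hold against the floor used and move with it: the log2 change of Cldn3 was -6.87 with the floor at the 50th percentile and -8.69 with no floor. At the floor on all 3 Zeb1 arrays were Bex1, at least 489-fold lower, Myl7 (at least 203-fold), Mapk13 (at least 183-fold), Mpzl2 (at least 147-fold) and Kdf1 (at least 102-fold). Other probe sets were at least 90.7-fold lower for Kcnk1, 13.9-fold for Kdf1, and 89.3-fold and 30.8-fold for Mpzl2.

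Among genes with at least 1 array of each group above the floor, the largest rises were those of Cdh17 and Cdx2, an intestinal cadherin and an intestinal transcription factor. Cdh17 went from 5.76 ± 0.434 to 11.93 ± 0.044 (SD, n = 3 each), at least 71.9-fold higher (adjusted p = 4.95e-09), and Cdx2 from 4.64 ± 0.330 to 10.70 ± 0.200, at least 66.6-fold higher (adjusted p = 8.11e-09), with 2 of the 3 control arrays at the floor. The log2 change of Cdh17 was 6.17, or 5.60 with the floor at the 50th percentile, and that of Cdx2 was 4.37 with that floor and 6.88 with no floor. The secreted protease Mmp10 was 57.0-fold higher, the oxygenase Cyp1b1 at least 56.4-fold, and the neuronal surface protein neuritin, Nrn1, 50.4-fold. Selenop, a plasma selenium carrier, was at least 50.3-fold higher, the small GTPase Gem at least 47.9-fold (log2 change 5.58, or 4.57 with the floor at the 50th percentile), ceruloplasmin (Cp) at least 43.4-fold and Rasgrp3, an activator of Ras-like GTPases, at least 43.3-fold. Cldn2, a claudin that forms ion-permeable pores, was 41.8-fold higher (7.31 ± 0.077 to 12.69 ± 0.054, adjusted p = 9.73e-11). Of the genes at the floor on all 3 control arrays, the stem cell transcription factor Sox2 was at least 77.3-fold higher, the decoy receptor Tnfrsf11b at least 71.0-fold, Mdfic at least 69.5-fold, the sulfotransferase Chst1 at least 59.4-fold and Khdrbs3 at least 52.4-fold. On other probe sets the rises were at least 5.2-fold for Tnfrsf11b, 16.1-fold for Cyp1b1, 19.4-fold for Rasgrp3 and 34.9-fold for Cdx2. For Cp they ranged from at least 6.13-fold to at least 55.1-fold, and for Cldn2 the rise was 7.60-fold.

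Epithelial genes fell as a body, with a few that rose. In the list of junction and polarity genes 29 of 34 tested members fell (30 adjusted over the list alone), 1 rose and 4 were not called, and the mean log2 change was -2.63 (camera adjusted p = 3.5e-15, adjusted p = 0.0521 with an estimated correlation). E-cadherin, Cdh1, the adhesion receptor of adherens junctions, fell by 4.01 on the log2 scale (16.1-fold, 14.18 ± 0.027 to 10.17 ± 0.145, adjusted p = 2.64e-10), and its signal in Zeb1 cells was still well above the floor. Crb3, an apical polarity protein, was 5.09-fold lower (10.62 ± 0.073 to 8.27 ± 0.202, adjusted p = 1.26e-07), and a second of its 3 probe sets was at least 157-fold lower, at the floor on all 3 Zeb1 arrays. Its log2 change was -4.20 with the mean of probe sets. The desmosomal cadherin Dsc2 was the single member that rose, by 1.12 (adjusted p = 0.00127), or by 0.36 relative to its neighbouring genes (adjusted p = 0.226).

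Among epithelial surface and trafficking genes 21 of 27 fell (22 adjusted over the list alone) and 3 rose, with a mean log2 change of -2.93 (camera adjusted p = 1.78e-09, adjusted p = 0.104 with an estimated correlation). S100a14, a calcium-binding protein, fell by 6.61 beside Rab25, whereas Cldn2 rose by 5.38 and the tetraspanin Tspan8 by 1.83. Of 9 keratins 5 fell (6 adjusted over the list alone) and 0 rose (camera adjusted p = 0.0045, adjusted p = 0.345 with an estimated correlation). Beside Krt7, Krt14 fell by 3.01, Krt20 by 2.33 and Krt80 by 2.02, but the abundant simple-epithelial keratin Krt18 had a log2 change of 0.03 (SE 0.057, adjusted p = 0.689; 14.69 ± 0.093 and 14.72 ± 0.073), or 0.19 relative to its neighbouring genes (adjusted p = 0.0217). Krt19, chosen after its value was seen, had a change of -0.04 and was not called, and its partner Krt8, chosen likewise, fell by 0.16. The median over keratins was -0.58 and the mean -1.83, so the mean rests on a few members.

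Epithelial transcription and splicing factors divided. Here 11 of 19 fell and 4 rose (11 and 4 adjusted over the list alone), with a mean log2 change of -0.58 and a median of -0.97 (camera adjusted p = 0.0187, adjusted p = 0.458 with an estimated correlation). Esrp1, an epithelial splicing regulator, was at least 86.2-fold lower (10.88 ± 0.108 to the floor, adjusted p = 1.12e-09), and the ETS factor Ehf was at least 15.6-fold lower. The 4 that rose were Sox2, Cdx2, Hnf4a (3.43) and Foxa2 (1.35). Gata6 fell by 0.76, and Foxa1 and Foxa3 had changes of -0.14 and -0.68 and were not called. Foxa1, Foxa2, Foxa3 and Gata6 were chosen after their values were seen. The call was lost when any 1 control array was left out, with adjusted p = 0.913 without control vector replicate 1, 0.807 without replicate 2 and 0.963 without replicate 3, because genes present in control cells alone then miss the filter of 3 arrays. The mean change was then 0.73, 0.72 and 0.65. It was also lost under the stricter filter, with 13 members, a mean of 0.12 and an adjusted p of 0.46, and with the mean of probe sets per gene (adjusted p = 0.0696). For keratins the call was lost under the stricter filter, which left 5 members (adjusted p = 0.0973).

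**Figure D2:**
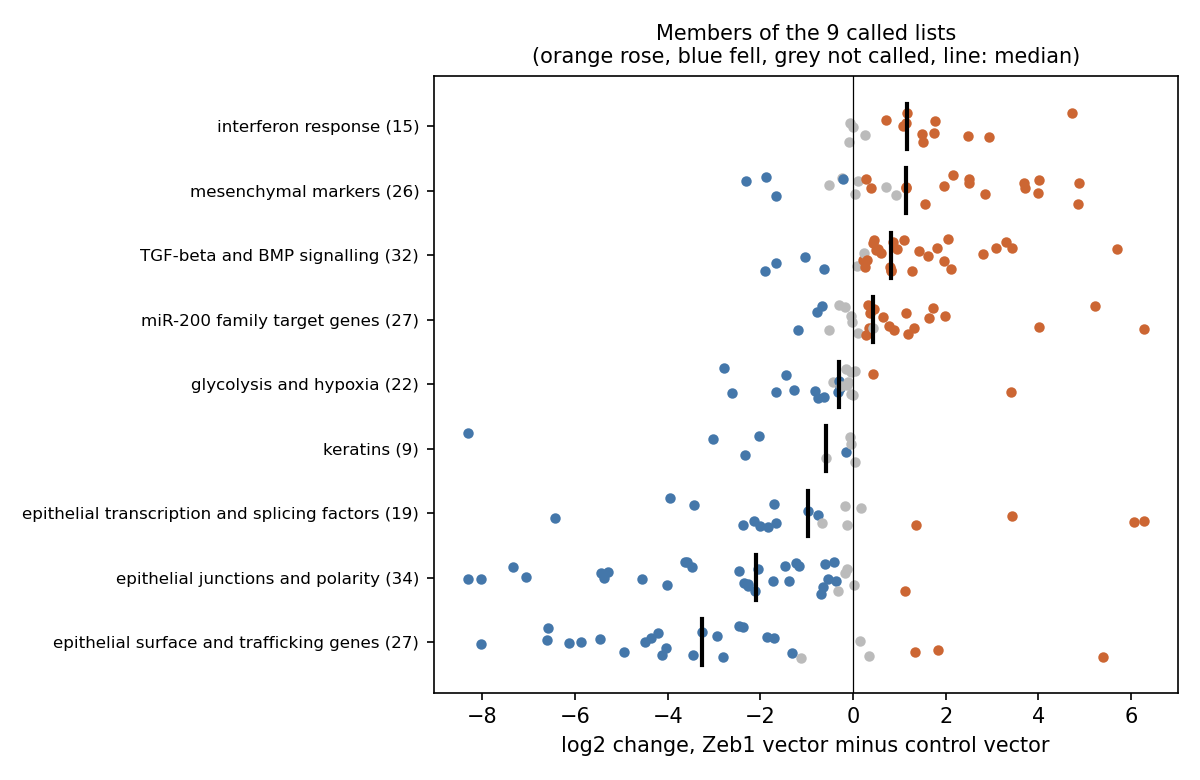
Log2 change (Zeb1 vector minus control vector) of every tested member of the 9 called lists, with the number of tested members in brackets, points in orange for members that rose, blue for those that fell and grey for those not called, and a black line at each list's median. The median is -3.26 for epithelial surface and trafficking genes, -2.09 for epithelial junctions and polarity, and 1.16 for the interferon response.

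Mesenchymal markers mostly rose. Of 26 tested markers 16 rose (17 adjusted over the list alone), 4 fell and 6 were not called, with a mean log2 change of 1.40 (camera adjusted p = 0.000185, adjusted p = 0.239 with an estimated correlation). N-cadherin, Cdh2, was 29.6-fold higher (7.82 ± 0.111 to 12.71 ± 0.112, adjusted p = 2.77e-10) and the intermediate filament vimentin, Vim, 7.25-fold higher (11.71 ± 0.121 to 14.56 ± 0.076, adjusted p = 1.43e-09). Fibronectin, Fn1, was 2.21-fold higher (adjusted p = 7.66e-05), and the transcription factors Snai2 and Foxf2 were 4.47-fold (adjusted p = 4.62e-05) and at least 16.1-fold (adjusted p = 4.57e-07) higher. The secreted ligand Wnt5a rose by 4.84, or by 3.20 with the floor at the 50th percentile. Acta2 fell by 1.88, and Tagln was at least 4.96-fold lower, with a log2 change of -0.43 with the floor at the 50th percentile.

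Snai1, a related repressor, was low in both groups (6.31 ± 0.249 and 6.42 ± 0.288, adjusted p = 0.789), and Twist1 lay at the floor on all 3 control and on 2 of the 3 Zeb1 arrays and was not tested. Zeb2, the paralogue of Zeb1, gave probe sets that disagreed. The one that stood for the gene, the brightest, had a log2 change of -0.52 (adjusted p = 0.13), called as a fall under quantile normalization (-0.62, adjusted p = 0.0436), while the other 3 rose, by at least 3.95 with control arrays at the floor (SE 0.255, adjusted p = 1.59e-06, 4.68 ± 0.409 to 8.64 ± 0.021), by 2.49 (adjusted p = 0.000504) and, also from the floor on a control array, by at least 2.27 (adjusted p = 0.000258). Without control vector replicate 1, 2 or 3 the gene was represented by another probe set and rose by 3.83, 4.19 and 3.83. Zeb2 is thus counted among the markers not called, although 3 of its 4 tested probe sets rose.

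**Figure D3:**
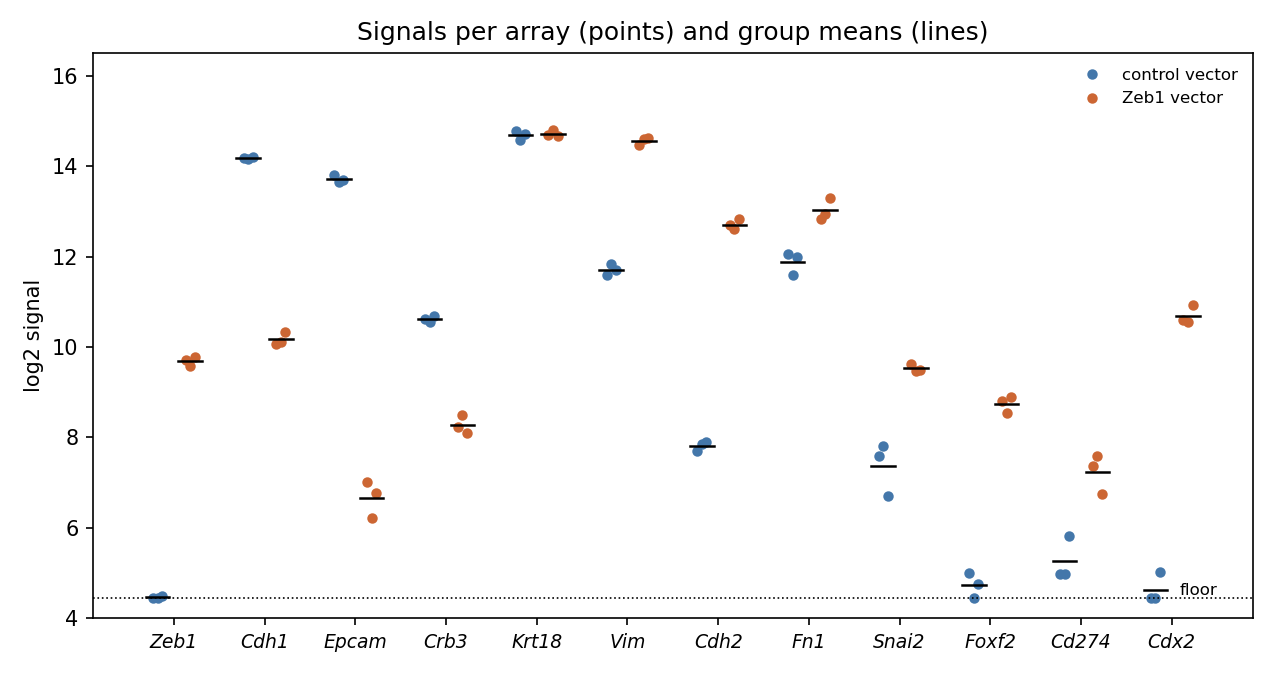
Log2 signal of 12 genes on each array, with control vector arrays in blue, Zeb1 vector arrays in orange, group means as black lines and the floor of 4.45 as a dotted line. Cdh1, Epcam and Crb3 are lower on every Zeb1 array than on any control array, Krt18 overlaps, and the rest are higher on every Zeb1 array.

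Taken per array, the mean of the junction and polarity list minus the mean of the mesenchymal list was 2.65 ± 0.024 in control cells and -1.39 ± 0.065 in Zeb1 cells (SD, n = 3 each). The difference of -4.04 had an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. The junction list went from 10.85 ± 0.013 to 8.22 ± 0.067 and the mesenchymal list from 8.20 ± 0.037 to 9.60 ± 0.059.

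**Figure D4:**
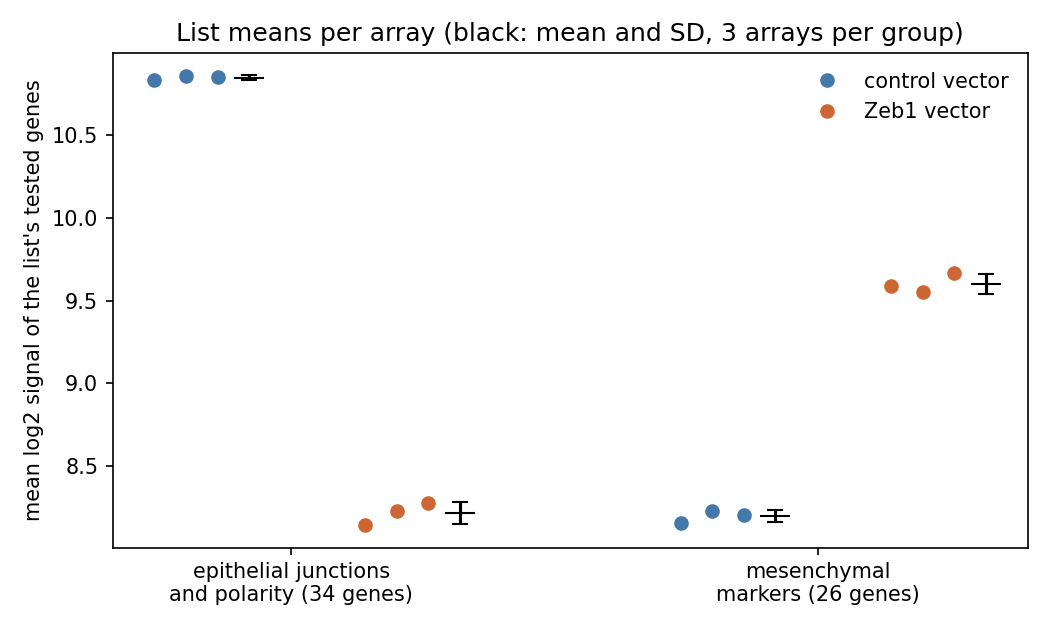
Mean log2 signal of the 34 tested junction and polarity genes and of the 26 tested mesenchymal markers on each array, with control vector arrays in blue, Zeb1 vector arrays in orange, and the mean and SD of 3 arrays in black. The junction mean is 10.85 in control cells and 8.22 in Zeb1 cells, and the mesenchymal mean is 8.20 and 9.60.

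Genes of TGF-beta and BMP signalling rose together: 26 of 32 rose (27 adjusted over the list alone), 4 fell and 2 were not called, with a mean log2 change of 1.07 (camera adjusted p = 5.75e-06, adjusted p = 0.292 with an estimated correlation). The ligand Bmp2 was at least 51.5-fold higher, from the floor to 10.13 ± 0.046, and Id3, a transcriptional inhibitor induced by BMP signals, rose by 3.42 (8.43 ± 0.211 to 11.85 ± 0.098). The latent TGF-beta binding protein Ltbp2 fell by 1.91 and the procollagen protease Bmp1 by 1.66.

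Genes commonly cited as miR-200 family targets mostly rose, 17 of 27 (17 adjusted over the list alone), with 3 that fell and a mean log2 change of 0.94 (camera adjusted p = 0.00325, adjusted p = 0.253 with an estimated correlation). The list holds Zeb1 itself, carried by the vector, and its largest member was Sox2. Cd274, the checkpoint ligand PD-L1, rose by 1.98 (SE 0.35, adjusted p = 0.000892, 5.26 ± 0.493 to 7.24 ± 0.434), or by 0.92 with the floor at the 50th percentile. The actin-severing protein Cfl2 fell by 1.18 and the receptor Notch1 by 0.78 (adjusted p = 0.0117). The change of Notch1 was -1.91 with the floor at the 50th percentile and -2.29 with the mean of probe sets, since its other probe set was at least 13.8-fold lower, and its call was lost with no filter (adjusted p = 0.0523). The list's call was lost without Zeb1 vector replicate 3 (adjusted p = 0.0557).

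Interferon-stimulated genes rose: 11 of 15 (11 adjusted over the list alone), with 0 that fell and a mean log2 change of 1.39 (camera adjusted p = 0.000262, adjusted p = 0.104 with an estimated correlation). Ifit2, an antiviral effector, was at least 26.5-fold higher and Rtp4 at least 7.63-fold higher, with log2 changes of 2.85 and 1.05 with the floor at the 50th percentile. The interferon-induced GTPases Igtp and Irgm1 rose by 2.49 and 1.77, a call lost for Igtp with no filter (adjusted p = 0.0864). Of 23 cytokines and chemokines 13 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.103), and the list was called up without control vector replicate 1 or 3 (adjusted p = 0.044 and 0.0402). The monocyte chemokine Ccl2 rose by 3.76 and Ccl5 by 3.27, while the granulocyte growth factor Csf3 fell by 3.72 and Cxcl16 by 3.28.

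Checkpoint and antigen presentation genes went both ways, 5 of 14 up and 4 down (5 and 4 adjusted over the list alone; camera adjusted p = 0.979, direction down against a mean of 0.10 and a median of 0.22). The peptide transporter Tap2 rose by 1.41 (adjusted p = 0.0261), a call lost without Zeb1 vector replicate 1, 2 or 3 (adjusted p = 0.0663, 0.0584 and 0.0583), and its rise was 0.80 without control vector replicate 1 and 0.77 with the floor at the 50th percentile. The class I heavy chain H2-K1 fell by 1.81 and the ectonucleotidase Nt5e by 1.66.

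Matrix genes changed without a common direction. Among matrix and crosslinking genes 8 of 31 rose and 11 fell (8 and 11 adjusted over the list alone; camera adjusted p = 0.979), with a mean of 0.13, a median of -0.03 and a camera direction of down. The large proteoglycan versican, Vcan, rose by 4.69 and Tgfbi, a TGF-beta-induced adhesion protein, by 3.48, beside the falls of Bgn and of the laminin chain Lamb3, which fell by 2.33. Other, lower probe sets stood for 2 of these genes when a Zeb1 array was left out: Vcan then rose by 2.50, 2.58 and 2.07 without Zeb1 vector replicates 1, 2 and 3, and Tgfbi by 1.63 without replicate 1 and 1.46 without replicate 3. For matrix proteases and inhibitors 9 of 20 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.583), with Mmp13 up by 5.34 beside Mmp10, and the urokinase gene Plau down by 3.55 and Adam8 by 2.23. Of 13 integrins 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.628). Itga6 rose by 0.65 and Itgb5 by 0.53, while Itgb4, the hemidesmosome subunit, fell by 2.91 and Itgb6 by 1.86, or by 0.87 with the floor at the 50th percentile. The other probe sets of Itgb5 rose by 1.09 to 1.66, and its call was lost with no filter (adjusted p = 0.0509).

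In the list of actin and contractility genes 17 of 39 fell and 9 rose (17 and 9 adjusted over the list alone; camera adjusted p = 0.15). The tropomyosin Tpm2 was 17.1-fold lower (12.93 ± 0.012 to 8.83 ± 0.101, adjusted p = 2.32e-10), and the non-muscle myosin Myh10 rose by 2.68 and the profilin Pfn2 by 0.79.

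Growth factor signalling lists were divided too. Receptor tyrosine kinases and ligands had 11 of 37 up and 10 down (11 and 10 adjusted over the list alone; camera adjusted p = 0.89). The ligands Fgf7 and Kitl rose by 3.32 and 2.35, the receptor Erbb3 fell by 4.04, and Epha1 was at least 8.48-fold lower. With the floor at the 50th percentile the log2 change of Epha1 was -1.21. In the PI3K list 8 of 22 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.838), with a mean of 0.10, a median of -0.08 and a camera direction of up. The adaptor Irs1 rose by 2.03 and the GATA cofactor Zfpm2 by 1.18, while the adaptor Irs2 fell by 1.69 and the regulatory subunit Pik3r3 by 1.05. The fall of Irs2 was 0.32 (adjusted p = 0.246) with the floor at the 50th percentile. For Wnt and Notch genes 7 of 27 rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.979), with a mean of 0.19, a median of -0.01 and a camera direction of down. The receptor Fzd7 rose by 2.72, and the ligand Wnt7b fell by 2.19 and the receptor Fzd1 by 0.84.

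Glycolysis and hypoxia genes fell as a list, 11 of 22, with 2 that rose (11 and 2 adjusted over the list alone) and a mean log2 change of -0.47 (camera adjusted p = 0.00225, adjusted p = 0.43 with an estimated correlation). Ndrg1, a hypoxia-induced gene, fell by 2.80 and the phosphofructokinase Pfkl by 2.62, while Egln3, a prolyl hydroxylase that is itself induced by hypoxia, rose by 3.41. The second phosphofructokinase that was called, Pfkp, rose by 0.43 (adjusted p = 0.0131), but its change was -0.11 relative to its neighbouring genes (adjusted p = 0.552). Of 21 cholesterol and fatty acid synthesis genes 11 fell and 7 rose (11 and 8 adjusted over the list alone; camera adjusted p = 0.383). The desaturase Scd1 rose by 2.55 and the regulator Srebf1 by 0.83, and the sterol enzymes Fdft1 and Lss fell by 1.65 and 1.28.

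Stress response genes had 11 of 25 up and 6 down (11 and 6 adjusted over the list alone; camera adjusted p = 0.361), with the antioxidant enzymes Nqo1 and Gclc up by 2.45 and 1.71, and Hmox1 and the chaperone Hspa1b down by 0.91 and 0.70. The call of Hmox1 was lost with no filter (adjusted p = 0.0608). For p53 targets and apoptosis genes 9 of 21 fell and 6 rose (9 and 6 adjusted over the list alone; camera adjusted p = 0.383). Perp, a desmosomal p53 target, fell by 3.58 and Gadd45b by 2.22, while the cell cycle inhibitor Cdkn2a rose by 2.06 and Ccng1 by 0.64, or by 0.26 relative to its neighbouring genes (adjusted p = 0.0848).

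The cell cycle list held 12 of 35 that fell and 6 that rose (12 and 6 adjusted over the list alone; camera adjusted p = 0.361, mean 0.02, median -0.06, direction down). Cyclin D2, Ccnd2, stood out with a 23.6-fold rise (7.03 ± 0.294 to 11.60 ± 0.13, adjusted p = 6.89e-09), against 0.52 for E2f1 and falls of 1.15 for Mybl2 and 0.81 for the replication factor Mcm3. Of 17 lung lineage genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.64, mean 0.05, median 0.31). Hnf4a rose by 3.43 and Id2 by 1.28, and the water channel Aqp5 fell by 2.59 and the surfactant lipid transporter Abca3 by 1.88.

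Ribosomal protein genes served as a reference list: 5 of 19 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.89), with a mean of 0.04 that became -0.0012 under quantile normalization and -0.019 under 75th percentile scaling. Rps6 rose by 0.49 and Rpl19 by 0.16, and Rps19 fell by 0.23 and Rps18 by 0.18. None of these 4 calls held relative to neighbouring genes, where their changes were 0.14, 0, 0 and 0.04. The neighbours' median that is taken off includes the gene itself, so the changes of 0 for Rpl19 and Rps19 arose by construction. With eBayes without trend the calls of Rpl19, Rps19 and Rps18 were lost (adjusted p = 0.144, 0.0616 and 0.0786). Rpl19 also lost its call with no filter (adjusted p = 0.0976), under the replicate block (adjusted p = 0.0542), under 75th percentile scaling (adjusted p = 0.286) and without control vector replicate 2 or 3 or Zeb1 vector replicate 2 or 3 (adjusted p = 0.056, 0.0726, 0.0676 and 0.0635).

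Markers of other cell types were mostly below the filter. Of 21 leukocyte markers 7 were tested, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.383): Cd14, a lipopolysaccharide co-receptor, by 2.29, and Cd8a by 0.45 (adjusted p = 0.017), a call lost without Zeb1 vector replicate 1 or 2 (adjusted p = 0.0543 and 0.0534). Of 4 tested endothelial markers Eng rose by 0.81 and Egfl7 fell by 0.96, of 3 tested fibroblast markers Fbln1 rose by 2.25 and Fbln2 fell by 3.21, and the counts were the same adjusted over the list alone. Without _s_at and _x_at probe sets Egfl7 had a change of 0.049 and was not called (adjusted p = 0.901). The single red cell gene tested, Hba-a2, had a log2 change of 0.38 and was not called (adjusted p = 0.0909), but was called with eBayes without trend (adjusted p = 0.0303). These 3 lists were too small for camera.

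Changes also ran along chromosomes. When 11838 tested genes were placed in chromosome order, 748 of 10854 windows of 50 neighbouring genes had a median log2 change beyond 0.438, the 95th percentile of the largest window median in 100 shuffled orders. These windows joined into 22 runs, 11 higher and 11 lower in Zeb1 cells. The longest run held all 299 tested genes of 1 chromosome, from Crem to Tmx3: their median change was 0.68, 85.6% were higher in Zeb1 cells, 211 rose and 17 fell. Zeb1, Cdh2, Dsc2 and Cd14 lie on it, with rises of 5.23, 4.88, 1.12 and 2.29. In the next longest, from Gm15850 to Ephx1, the median over 183 genes was 0.42, and in the longest lower run, from Mir124a-1hg to Tmtc4, it was -0.49 over 128 genes.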

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

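The test of changes relative to neighbouring genes was chosen after the runs of neighbouring genes had been seen. The bounds first set on the share of calls kept (67% and 80%) left it undecided. A further rule was added after its value was known: over 5% of tested genes still called would argue against copy number as the cause of all changes. The other tests in this part were written before their results were seen.

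Probe sets with no or several gene symbols lay outside the comparison of genes. Of 2797 that passed the filter, 405 were higher in Zeb1 cells at adjusted p under 0.05 in limma and 325 were lower, 26.1% in all, and 152 of the first were at least 2-fold higher. They drew attention because they show signal above the control arrays in data that the gene comparison leaves out. Their share called was lower than the 50.5% of the tested genes.

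About 50.5% of the tested genes changed. The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05: the real split called 6004 genes, 1 of the 10 splits called as many, and the highest other called 0. Each other split mixes the groups, so the difference between them widens its spread within groups. The count of 0 therefore gives no support. The choice among scalings did not account for most calls: at least 94.0% kept their direction and significance under quantile normalization and 75th percentile scaling. These scalings also bring the arrays to a common level. A difference in total RNA between the groups would go unseen under each of them, so scaling as such was not excluded. Shifts shared by 51 neighbouring genes did not account for all changes: relative to neighbouring genes 5349 genes were still called, 45.0% of those tested, and 76.1% of the calls were kept. The 45.0% met the added rule against copy number as the cause of all changes. That rule cannot decide it, since only shifts that neighbours share are removed, and copy number changes of shorter stretches would stay called. Gene copy number that differs between the lines may have contributed and stays open. Windows of neighbouring genes that shifted beyond shuffled orders held 22.0% of the called genes (1317 of 5990), between the 10% and 50% set as bounds. They also held 2043 of all 11838 placed genes, called or not, and were picked by these same changes. The share therefore cannot tell how much copy number contributed. DNA was not analysed here, and the expression of Zeb1 named by the design was not tested apart from the line.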

How the results depend on the processing

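The floor at the 50th percentile and the changes relative to neighbouring genes were chosen after seeing the data; the other alternatives were chosen before the data were examined. Called genes numbered 4730 (stricter filter, 7324 genes tested) to 6212 (array weights) over the alternatives, against 6004, and 5127 to 5583 with 1 array left out. Genes changed at least 2-fold numbered 1137 under the stricter filter, against 1880, since fewer genes were tested, and 1627 to 1951 under the others. The 9 called lists became 0 with camera at an estimated correlation and 20 with fry, which does not compare a list with other genes, and 7 to 10 otherwise. Cholesterol and fatty acid synthesis genes were added relative to neighbouring genes (adjusted p = 0.0238, range over the alternatives 0.0238 to 0.568), and cytokines and chemokines without control vector replicate 1 or 3 (0.044 and 0.0402, range 0.0402 to 0.381). The epithelial minus mesenchymal shift lay between -4.97 and -3.44, and Zeb1 on its most changed probe set between 3.37 (floor at the 50th percentile) and 5.79 (no floor). Under quantile normalization 97.0% and under 75th percentile scaling 94.0% of the calls were kept in the same direction with 0 reversed; under the latter 46.8% of the calls were rises, against 52.3%.

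With the replicate number as a replicate block 5877 genes were called, 1898 at least 2-fold, and the 9 lists kept their calls. Deviations of same-numbered arrays correlated at 0.039, -0.027 and -0.069, so the numbers do not pair the arrays, and Rpl19 alone among the named genes lost its call (adjusted p = 0.0542).

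Over 129 named genes, 2384 of 2431 values kept direction and side of the threshold, 30 lost the call, 3 gained it and 14 reversed. With no filter, where more genes share the adjustment, calls were lost for Itgb5, Notch1, Hmox1, Irs2, Igtp, Rpl19 and Tap2 (adjusted p = 0.0509, 0.0523, 0.0608, 0.0698, 0.0864, 0.0976 and 0.146). With eBayes without trend they were lost for Tap2, Rps19, Rps18 and Rpl19 (0.0584, 0.0616, 0.0786 and 0.144) and gained for Hba-a2 (0.0303); Pfkp lost its call with the mean of probe sets (0.0969) and Cd8a without _s_at and _x_at probe sets (0.188). Zeb2 (-0.52) became 2.05 with the mean of probe sets, 2.31 with the floor at the 50th percentile, and -0.67 to 4.19 with 1 array left out, because other probe sets then count. Values near 0 turned for Krt18 (-0.0047 under quantile normalization, -0.026 under 75th percentile scaling, -0.018 to 0.073 with 1 array left out) and Snai1 (-0.014 to 0.27 with 1 array left out). Egfl7 was 0.049 without _s_at and _x_at probe sets, and Pfkp (-0.11) and Rps18 (0.041) turned relative to neighbouring genes, where the shared shift was removed. With 1 array left out a gene present in 1 group alone can miss the filter of 3 arrays, which lowers these counts by construction. Signal over background limits genes near the floor: their folds are bounds and vary with the floor.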

Other observations

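The tests of the changes of leukocyte and of epithelial transcripts and of all measured intestinal genes for gut cells were chosen after the results they bear on had been seen. For all measured intestinal genes the rule was written after their median had been computed. The tests of the intestinal and neural lists were written before their members' results were seen, though the lists were made because of the genes below.

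Genes known from the gut were among the largest rises, Cdh17 with at least 71.9-fold and Cdx2 with at least 66.6-fold, beside Sox2 with at least 77.3-fold. A list of 41 other intestinal genes was mostly below the filter: 6 were tested, 1 rose (Myo7b, by 0.96) and 5 were not called, so that 16.7% had risen. This shows no shared rise within these 6, which cannot speak for intestinal genes as a group. Cdh17 and Cdx2 were outside this list. The list was also written without members of the earlier lists, and so leaves out any gut genes among those, whichever way they went. Hnf4a, counted above among epithelial factors and lung lineage genes, rose by 3.43, Cldn2 by 5.38 and Tspan8 by 1.83, while Krt20 fell by 2.33. The share of 16.7% and the median given next do not cover these genes. Over all 39 measured genes of the list the median log2 change was 0.036 (median absolute deviation 0.35), against 6.06 for Cdx2. This median cannot decide on gut epithelial cells in the Zeb1 cultures, since a single kind of gut cell need not express most of the list. The largest change was 1.015 (Fcgbp), which argues against gut cells that bring any of these 39 transcripts up as far as Cdx2. A line of gut origin without these transcripts stays open: the median change of Vil1, Epcam, Krt20, Cldn3, Cldn4 and Cldn7 was -7.20, but 4 of these 6 were among the largest falls already seen, which fixed that outcome. Whether the rises follow from Zeb1 or from the selection of stable lines was not tested.

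The 11 interferon-stimulated genes that rose had a median log2 change of 1.51. Leukocytes in the Zeb1 cultures would bring Ptprc, Tyrobp, Laptm5, Coro1a and Fcer1g along, but the median change of these 5 was 0.22 (median absolute deviation 0.76). This does not settle it, since 3 of the 5 were below the filter, where signal and background are hard to part. Of these, Ptprc and Coro1a had log2 changes of -0.30 and -0.45, and Tyrobp of 0.73. Laptm5 and Fcer1g were tested and not called. In the leukocyte list fixed earlier, 2 of 7 tested markers rose, Cd14 by 2.29, more than the interferon median, and Cd8a by 0.45, and 5 were not called. Cd14 already had a log2 signal of 9.86 in control cells and lies on the chromosome whose tested genes shifted upward together. A first test on signal levels, whose result went against leukocytes, was dropped, since levels of different probe sets are not comparable. Leukocytes and an effect of Zeb1, named by the design, both remain open.

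Nrn1, a gene of neurons, was among the largest rises, and a list of 38 other neural genes was tested for a shared rise. Of 12 tested members 5 rose and 2 fell, with a mean of 0.67 and a median of -0.13, and a shift of the list against other genes was not detected with camera (p = 0.251, n = 12 genes), though fry, which makes no such comparison, gave p = 0.000337 (n = 12 genes, direction up). The risen members included the axon growth proteins Dpysl3 (3.72) and Dpysl2 (1.69), the splicing regulator Celf4 (3.01) and the synaptic protein Syn1 (1.95), all chosen after their values were seen.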
